A study of Danio rerio with 14 samples.

How the data were processed

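Messenger RNA was sequenced from F1 zebrafish embryos collected 5.5 hours after fertilization, when gastrulation begins, from AB wild type parents that had been exposed to gamma radiation during gametogenesis or had not. Per the labels, the dose rates were 8.7 and 53 mGy/h, the parents were bred 1 month after exposure (called 0 yr) and unexposed parents and those exposed at 8.7 mGy/h gave a further brood after 1 year (1 yr). Each sample held 100 embryos, and 1.5 µg of total RNA went into a poly(A)-selected, non-directional library, per the labels' protocols, so reads do not mark the strand of origin and overlapping antisense genes cannot be separated. The labels give 14 libraries in 5 groups. There were 3 libraries each at 53 mGy/h (0 yr), 8.7 mGy/h (0 yr), 8.7 mGy/h (1 yr) and control (1 yr), and 2 in the control at 0 yr, where 1 sample was lost during RNA extraction. Nothing in the labels says which parents or breeding day each library came from, so spread between libraries may not cover spread between clutches.

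Trim Galore 0.4.2, FastQC 0.11.5, STAR 2.5.2b, DESeq2 and the build GRCz10 are named in the submitters' processing notes, without their roles or settings. The 3 deposited tables each set 1 exposed group against its control and hold 1 value per group and gene. The authors gave each group as log2 RPM and as RPM, reads scaled to library size, per the file headers. The authors' table also gives the exposed over control ratio, a signed fold change (negative where the exposed value is lower), which is a score without values between -1 and 1, and an FDR, which is an adjusted p-value per the file headers. The test behind the FDR is not named in the tables, and DESeq2 is the only test that the submitters' processing notes name. The tables carry no per-library value, standard error, test statistic or unadjusted p. The tables list 13714, 13263 and 12502 genes at 53 mGy/h (0 yr), 8.7 mGy/h (0 yr) and 8.7 mGy/h (1 yr), with 12120 in all 3. The control values of the 0 yr tables were identical, so those comparisons share their control libraries.

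Depth was recovered from the pooled values. Each group's log2 RPM was taken as the mean over libraries of the log2 of whole reads in RPM, so the value times the number of libraries gives a product of whole reads. With the number of libraries in the labels, 100% of the 150 lowest values at or above 0.4 RPM came out whole (tolerance 0.04) in each group, and with the wrong number 22.0 to 28.7% did. The smallest geometric mean depth that fits was 27.7 M reads (megareads) for control (0 yr), 27.3 M for 53 mGy/h (0 yr), 25.7 M for 8.7 mGy/h (0 yr), 22.6 M for control (1 yr) and 23.6 M for 8.7 mGy/h (1 yr). Depth of single libraries and their spread are unknown, and no interval is given for single genes.

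A gene was called changed at an FDR under 0.05 as deposited, with the direction from the difference of the log2 RPM columns, called the log2 change. The deposited FDR followed the size of the change closely. In 50 bins of mean log2 RPM, 1 upper and 1 lower limit on the log2 change gave the calls with 375 exceptions among 5978 calls at 53 mGy/h, 0 yr and 185 among 5301 at 8.7 mGy/h, 1 yr. The middle of these limits lay at 0.12 and -0.09 on the log2 scale, so the authors' test used another zero than RPM, and no called gene lay between 0 and that middle. Counts, medians and overlaps were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The planned tests of differences between comparisons needed standard errors and were not possible, so differences in response are given as sizes without a test. The lists of genes were fixed before the data were examined, as were the thresholds and the rule for named genes. The 21 lists cover the p53 pathway, DNA repair, antioxidants, apoptosis, cell cycle, maternal transcripts, mesoderm and endoderm, dorsoventral patterning, ectoderm, enveloping layer, yolk syncytial layer, germ cells, retinoic acid and hox genes, chromatin, heat shock and unfolded protein response, gastrulation movements, inflammation, later-stage tissues, adult gonad, sperm and blood, ribosomal proteins and mitochondrially encoded transcripts. Where several gene identifiers in a table shared a listed symbol, each counted as a gene. For each list and direction, the called members were set against all other genes in the table with a two-sided Fisher's exact test, and p was adjusted by the Benjamini-Hochberg method over the 42 tests of a comparison. A list's median log2 change was set beside the central 95% of 10000 random lists matched on mean expression in 10 bins. The planned list test on a per-gene statistic could not be run, and cameraPR of limma 3.58.1 (R 4.3.3) on the log2 changes was used as an alternative. Counts adjusted over the list alone and tests with an estimated correlation could not be made without unadjusted p or library values. Genes are not independent, so the Fisher p of a co-regulated list is too small. Random lists were drawn gene by gene, so their spread is too narrow for such a list.

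Named genes were the 8 largest rises and falls among called genes in the upper part of expression with an informative symbol, the called members of each list with the smallest FDR (up to 2 per direction, all where 5 or fewer were called), cdkn1a, mdm2, hnf4a and cyp26a1 whatever their result, and up to 5 genes called in all 3 comparisons in the same direction. Some genes that this rule takes are not reported here. Symbols are those of the tables, and 495, 461 and 410 of the listed symbols in the same order as above are numbered as 1 of several copies, whose reads may be split between them. Coordinates are the authors', in GRCz10 per the submitters' processing notes, and exon and intron annotation was not used here. For the shared 0 yr controls, 100 data sets of unchanged groups were simulated. Their spread was set from the median absolute deviation of the 8.7 mGy/h, 0 yr changes in 20 expression bins.

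The list test was tested on simulated calls with lists of 40 genes whose falls were 3 times as frequent as in other genes. Such lists were found in 100% of 100 draws at the call rate of the 53 mGy/h comparison (13714 genes) and in 100% at that of 8.7 mGy/h, 1 yr (12502 genes), but in 2% at that of 8.7 mGy/h, 0 yr (13263 genes), where 3% of unchanged lists passed. Alternatives were an FDR under 0.01 or 0.1, a log2 change of at least 1, a mean RPM of at least 10, centring on the median log2 change of the upper part of expression, leaving out numbered copies and cameraPR.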

Results

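The data compare F1 zebrafish embryos at 5.5 hours after fertilization from gamma-irradiated and from unexposed parents. The design asks how gene expression in the offspring differed 1 month after parental exposure at 2 dose rates, 8.7 and 53 mGy/h, and whether a difference was present when the parents exposed to 8.7 mGy/h bred again 1 year later. The 14 libraries fall into groups of 3, except the 0 yr control with 2. Geometric mean depth was at least 22.6 to 27.7 M reads (megareads) per group. Every expression level below is the authors' value for a group in RPM, for which the deposited tables give no spread between libraries.

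At 53 mGy/h, 0 yr, genes that pattern the early embryo fell and a set of other genes rose by similar factors. The chemokine receptor gene cxcr4a fell from 117 RPM in controls to 3.54 RPM, the G1 cyclin ccnd1 from 439 to 34.3 RPM and the transcription factor mycn from 61.3 to 4.71 RPM. The SH2-domain gene sh2d5 rose from 5.56 to 65.8 RPM and luzp1 from 8.90 to 96.7 RPM. Of the genes in the authors' deposited table, 5978 of 13714 genes (43.6%) passed an FDR of 0.05, 3036 up and 2942 down, and 1864 and 1701 of them changed at least 2-fold. The median fold of called genes was 2.24 up and 2.41 down.

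Among the largest falls, evpla, a gene of the envoplakin family, had a log2 change of -3.97, ca9 of -3.80, foxd5 of -3.36, nav2b of -3.34 and the keratin gene krt5 of -3.31. The authors' deposited table lists cxcr4a 33.1-fold lower with an FDR of 0, ccnd1 12.8-fold lower with an FDR of 8.69e-31, and krt5 9.90-fold lower with an FDR of 0.00448. Among the largest rises, hivep3b rose by a log2 change of 3.91 (1.71 to 25.7 RPM), mkl1b by 3.45, sbf2 by 3.41, stard7, which encodes a lipid transfer protein, by 3.38, gatsl3 by 3.31 and bicc1a by 3.29. An FDR of 0 was listed for 29 genes in the authors' deposited table and is a rounded value. The cxcr4a gene lies on chromosome 6, from 12687144 to 12688869 in GRCz10, and sh2d5 on chromosome 11 from 37371775 to 37383761. The median log2 change over the upper part of expression was 0.11, near the 0.12 around which the authors' calls were centred.

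**Figure D1:**
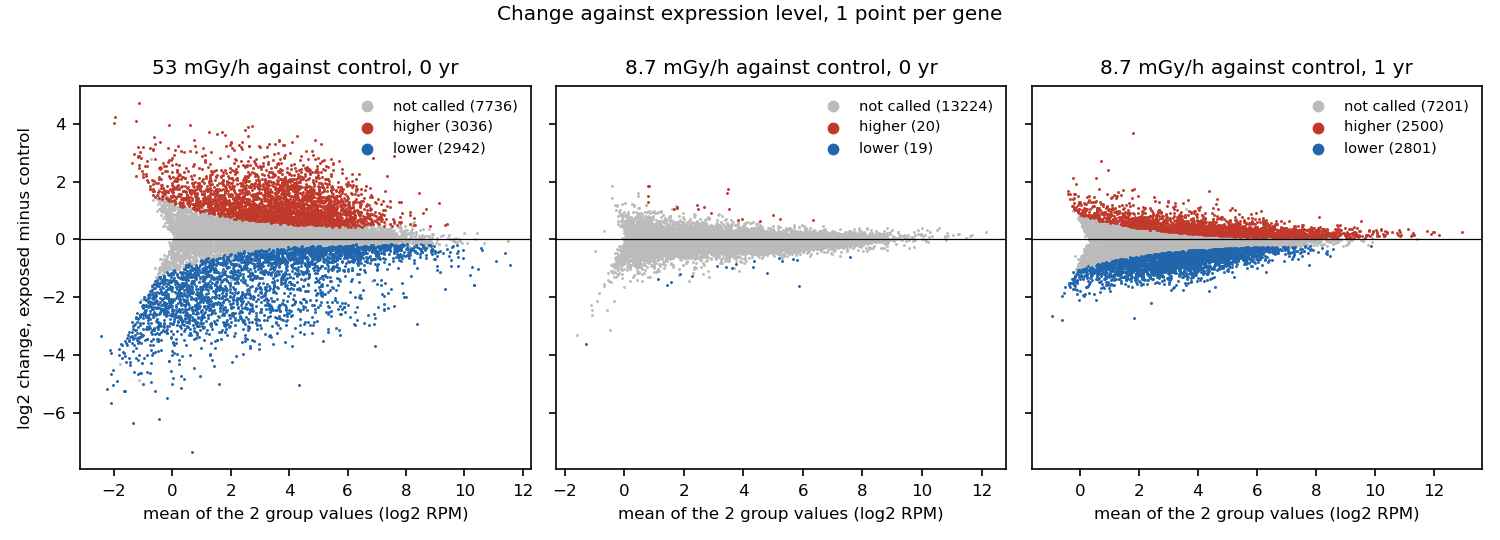
Log2 change of each listed gene (exposed minus control, vertical axis) against the mean log2 RPM of both groups (horizontal axis), with called genes in red (higher) and blue (lower) and others in grey. Called genes number 5978 at 53 mGy/h, 0 yr, 39 at 8.7 mGy/h, 0 yr and 5301 at 8.7 mGy/h, 1 yr.

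The lists of lineage genes fell at 53 mGy/h. Of 28 mesoderm and endoderm genes 21 fell and 4 rose (adjusted p = 2.19e-08, Fisher's exact test for falls), with a median log2 change of -1.83. The ligand gene apela, which guides mesendodermal cells, fell from 20.3 to 0.13 RPM, while eomesa, a T-box gene that is also supplied by the mother, rose from 32.7 to 155 RPM and smad2 from 66.2 to 182 RPM. Of 49 dorsoventral patterning genes 35 fell and 5 rose (adjusted p = 1.90e-12, Fisher's exact test), including wnt11 (68.8 to 17.7 RPM) and tfap2a (41.5 to 5.36 RPM), whereas otx1b rose from 24.1 to 76.3 RPM and etv5a from 38.1 to 184 RPM. Of 22 ectoderm and neural genes 17 fell and 1 rose (adjusted p = 2.49e-07, Fisher's exact test), among them the neural gene sox3 (124 to 13.4 RPM), and the gene that rose was six3a, at 0.19 and 1.07 RPM.

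Genes of the extraembryonic layers fell as well. In the enveloping layer list, the outer epithelium of the embryo, 23 of 26 genes fell and krtcap2 alone rose (adjusted p = 7.21e-12, Fisher's exact test), and grhl1, an epidermal transcription factor, fell from 30.5 to 3.79 RPM. In the yolk syncytial layer list 13 of 22 genes fell and 3 rose (adjusted p = 0.00064, Fisher's exact test). Its regulators mxtx1 and mxtx2 fell from 31.9 to 4.90 RPM and from 46.8 to 11.2 RPM, while creb3l3l rose from 2.97 to 17.8 RPM and fn1a from 28.0 to 57.0 RPM. The endodermal and yolk regulator hnf4a fell from 35.8 to 8.58 RPM. Of 40 genes of gastrulation movements 20 fell and 4 rose (adjusted p = 0.000321, Fisher's exact test), with prickle1b falling from 52.5 to 10.5 RPM and ezrb rising from 58.6 to 114 RPM.

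The lists of cell cycle genes, ribosomal proteins and mitochondrially encoded transcripts also had more falls than other genes by the Fisher test. Of 56 cell cycle and replication genes 30 fell and 9 rose (adjusted p = 7.93e-07, Fisher's exact test). The topoisomerase gene top2a fell from 65.3 to 18.5 RPM, but the mitotic and early embryonic cyclins ccnb2 and ccna1 rose from 198 to 601 RPM and from 367 to 873 RPM. Ribosomal protein genes fell in 56 of 74 cases and rose in none (adjusted p = 1.12e-21, Fisher's exact test), with a median log2 change of -0.42, as in rpl13a (112 to 67.6 RPM). Of 13 mitochondrially encoded transcripts 7 fell (adjusted p = 0.0437, Fisher's exact test), such as mt-nd3 (79.4 to 60.5 RPM). With cameraPR at a correlation of 0.05 the lists of cell cycle (adjusted p = 0.151), gastrulation movements (0.0881), ribosomal proteins (0.304) and mitochondrial transcripts (0.784) were not past the threshold, and the mitochondrial list was not at 0.01 either (0.672).

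The p53 pathway list had 10 rises and 4 falls among 26 genes and did not pass (adjusted p = 0.183 for rises, Fisher's exact test), but its median log2 change of 0.58 lay above the central 95% of matched random lists (-0.09 to 0.39), and cameraPR shifted it up at a correlation of 0.01 (adjusted p = 0.0286) and by rank (0.0238), not at 0.05 (0.151). The cell cycle inhibitor cdkn1a rose from 4.06 to 19.1 RPM, mdm2 from 48.5 to 118 RPM and mdm4 from 10.3 to 78.1 RPM, and gadd45ba fell from 22.6 to 5.14 RPM. The authors' deposited table gives an FDR of 0.00813 for cdkn1a and 0.000132 for mdm2. Of 62 DNA repair genes 12 rose and 18 fell, with atr rising from 5.91 to 31.1 RPM, and the median of the list (-0.01) lay just below the central 95% of matched random lists (0.01 to 0.36). Maternal transcripts (10 rises and 7 falls of 39) and germ cell genes (5 and 3 of 22) did not pass as lists, and the germ plasm genes tdrd6 and buc rose from 9.48 to 79.7 RPM and from 44.3 to 314 RPM, and the maternal SoxB1 gene sox19b rose by a log2 change of 2.90, while org fell from 58.6 to 19.7 RPM, ctcf from 1199 to 633 RPM, cxcr4b from 62.1 to 8.25 RPM and piwil2 from 32.8 to 22.0 RPM. The retinoic acid list had 4 rises and 7 falls of 21, and cyp26a1, which degrades retinoic acid, fell from 22.2 to 10.6 RPM.

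The remaining lists did not pass the test at 53 mGy/h. Antioxidant genes had 4 rises and 3 falls of 31, with txnrd1 rising from 55.3 to 132 RPM. Apoptosis genes had 5 and 6 of 30, chromatin genes 14 and 15 of 69, with brd2b rising (13.3 to 43.6 RPM) and its paralogue brd2a falling (327 to 101 RPM), heat shock and unfolded protein genes 7 and 15 of 45, and inflammation genes 8 and 8 of 28. Of the later-stage tissue markers 2 were listed and none was called. Of the adult gonad, sperm and blood genes 7 were listed, 2 rising and 2 falling, and cyp17a1 was at 41.0 and 62.3 RPM.

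**Figure D2:**
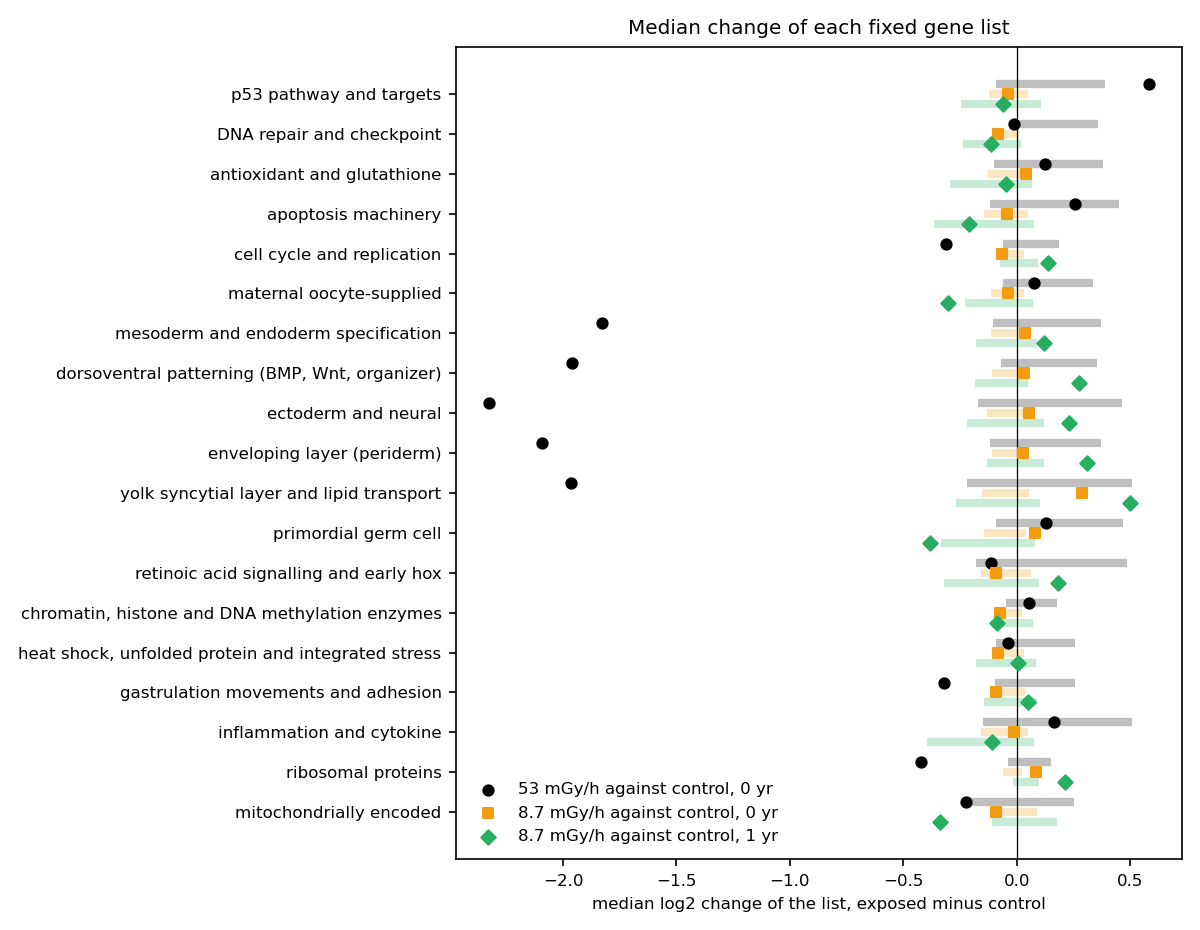
Median log2 change of each fixed list (points, horizontal axis) at 53 mGy/h, 0 yr (black), 8.7 mGy/h, 0 yr (orange) and 8.7 mGy/h, 1 yr (green), with bars for the central 95% of random lists matched on mean expression. The mesoderm and endoderm list stands at -1.83 at 53 mGy/h, 0 yr and at 0.12 at 8.7 mGy/h, 1 yr.

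At 8.7 mGy/h, 0 yr, few genes were called changed. The ribonucleotide reductase subunit gene rrm2 fell from 103 to 33.4 RPM, the Polycomb-associated gene jarid2b from 41.6 to 18.7 RPM and the fibronectin gene fn1a from 28.0 to 14.3 RPM. The aldehyde dehydrogenase gene aldh3a1 rose from 8.01 to 16.6 RPM and the translation factor gene eif5 from 65.0 to 103 RPM. Of the genes in the authors' deposited table, 39 of 13263 genes (0.294%) passed, 20 up and 19 down, 13 and 9 of them at least 2-fold. At least 2-fold changes, called or not, numbered 111, and the largest uncalled one had a log2 change of 3.29 in size. At 1 yr they numbered 737, of which 130 up and 598 down were called. Changes of at least 2-fold, called or not, were thus fewer at 0 yr than at 1 yr. Few calls alone do not show how many smaller changes there were.

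The other named rises were ODF3L2 (1 of 2), from 6.11 to 20.7 RPM, mcm3l, maza, usf1l and A2ML1 (9 of 13), all with log2 changes of 0.65 to 0.71 except the 1.76 of ODF3L2 (1 of 2). The other named falls were rbm45, with a log2 change of -0.95, rnf213a with -0.75, tmprss4a with -0.74, cited2, a transcriptional coregulator, with -0.70 and acbd3 with -0.67. The authors' deposited table gives an FDR of 5.91e-11 for rrm2, 2.55e-05 for aldh3a1 and 0.0018 for fn1a. Of the genes given in every comparison, cdkn1a stood at 4.06 and 3.53 RPM, mdm2 at 48.5 and 54.0 RPM, hnf4a at 35.8 and 44.6 RPM and cyp26a1 at 22.2 and 22.1 RPM, with an FDR of at least 0.872 in the authors' deposited table.

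No fixed list passed the Fisher test in this comparison. At this call rate the test found simulated lists with 3 times the falls in only 2% of draws, even without adjustment. The test could therefore not have shown such an enrichment here. Called members were rrm2 in the cell cycle list and fn1a in the yolk syncytial layer and gastrulation lists. The adult gonad, sperm and blood list was fixed with odf3l2. The called gene ODF3L2 (1 of 2) carries a numbered symbol and was not counted in it. The medians of the ribosomal protein list (0.09) and of the yolk syncytial layer list (0.29) lay above all 10000 matched random lists. Those of the germ cell (0.08), dorsoventral (0.03) and antioxidant (0.04) lists lay above the central 95% and that of the chromatin list (-0.07) just below it. With cameraPR on the log2 changes at a correlation of 0.01, chosen after seeing the data, 4 lists were shifted up and 1 down. At a correlation of 0.05, 2 were shifted up and 0 down. These 2 were the yolk syncytial layer list (adjusted p = 0.0153) and the later-stage tissue markers (0.0129), of which 3 genes were listed and none called, with a median log2 change of 0.36 inside the central 95% of matched random lists (-0.65 to 0.45) and an adjusted p by rank of 0.501. The ribosomal protein list was not past the threshold at 0.05 (adjusted p = 0.203) but was by rank (1.12e-05), as was the yolk syncytial layer list (0.000916), and the enveloping layer list (0.101) and the heat shock list (0.191), which were shifted up and down at 0.01, did not pass at 0.05.

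At 8.7 mGy/h, 1 yr, the lineage, cell cycle and ribosomal protein lists had more rises than other genes by the Fisher test, and many other genes fell. The neurogenic Delta ligand gene dld rose from 15.5 to 33.2 RPM, the dorsoventral gene szl by a log2 change of 1.09 and the carnitine transporter gene slc22a5 from 15.5 to 40.4 RPM. The polyadenylation factor gene cpeb1b fell from 38.8 to 11.4 RPM and the kinase gene mknk2a from 42.6 to 13.7 RPM. Of the genes in the authors' deposited table, 5301 of 12502 genes (42.4%) passed, 2500 up and 2801 down. At least 2-fold changes were found for 130 genes up and 598 down, and the median fold was 1.25 up and 1.64 down. The calls were centred on a log2 change of -0.09 rather than 0, and relative to that value the median change of called genes was 0.42 up and -0.62 down. The falls lay in genes of lower expression (median of the mean RPM 11.2, against 26.0 for the rises), and among genes with a mean RPM of at least 10 there were 1776 up and 1507 down.

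Further large rises were those of the heat shock gene hsp90aa1.2 by a log2 change of 1.69, cyp2x6 by 1.27, SLC47A1 (5 of 6) by 1.25, fetub by 1.23 and the laminin gene lama1 by 1.12. Further falls were those of cttnbp2, with a log2 change of -1.76, sh2d5 with -1.66, afap1l1a with -1.56, AKAP13 (2 of 2) with -1.51 and nrip1b with -1.46. The authors' deposited table gives slc22a5 2.61-fold higher with an FDR of 1.93e-43 and mknk2a 3.11-fold lower with an FDR of 3.06e-25. The slc22a5 gene lies on chromosome 21 from 45634836 to 45646180 in GRCz10.

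Of 36 mesoderm and endoderm genes 16 rose and 4 fell at 1 yr (adjusted p = 0.00565, Fisher's exact test), including cdx4 (6.30 to 13.2 RPM), while smad2 fell from 63.4 to 38.5 RPM. Of 54 dorsoventral genes 31 rose and 4 fell (adjusted p = 2.11e-08, Fisher's exact test), with gata2a rising from 29.1 to 49.9 RPM and etv5a and otx1b falling from 63.7 to 36.7 RPM and from 26.7 to 13.9 RPM. Of 21 ectoderm and neural genes 13 rose and her5 alone fell (adjusted p = 0.000191, Fisher's exact test), and sox2 rose from 17.8 to 37.0 RPM. In the enveloping layer list 20 of 29 rose and 2 fell (adjusted p = 1.05e-07, Fisher's exact test), with anxa1a rising from 26.9 to 54.3 RPM. In the yolk syncytial layer list 19 of 26 rose and 2 fell (adjusted p = 7.92e-08, Fisher's exact test), with the apolipoprotein gene apoeb rising from 592 to 929 RPM and fn1a falling from 14.6 to 9.12 RPM.

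Cell cycle genes rose in 32 of 56 cases and fell in 10 (adjusted p = 2.02e-08, Fisher's exact test), with the replication helicase genes mcm6 and mcm3 rising from 80.3 to 124 RPM and from 155 to 221 RPM and ccna1 falling from 295 to 161 RPM. Ribosomal protein genes rose in 69 of 74 cases and fell in none (adjusted p = 6.34e-41, Fisher's exact test), with a median log2 change of 0.21, as in rpl35a (55.7 to 74.9 RPM). Heat shock and unfolded protein genes (16 rises and 7 falls of 45) and genes of gastrulation movements (14 and 5 of 38) passed narrowly for rises (adjusted p = 0.0492 for each, Fisher's exact test). Of 13 mitochondrially encoded transcripts 7 fell and none rose (adjusted p = 0.0492, Fisher's exact test), with mt-nd5 falling from 183 to 120 RPM. With cameraPR at a correlation of 0.05 the lists of cell cycle (adjusted p = 0.215), mesoderm and endoderm (0.0712), heat shock (0.184), gastrulation (0.336) and mitochondrial transcripts (0.503) were not past the threshold.

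The p53 pathway list had 2 rises and 4 falls of 26 genes at 1 yr and did not pass, with btg2 falling from 188 to 142 RPM and with a log2 change of -0.24 in cdkn1a and mdm2 at 45.1 and 45.7 RPM. Germ cell genes had 2 rises and 10 falls of 22 (adjusted p = 0.0569 for falls, Fisher's exact test), with tdrd1 falling from 18.6 to 7.78 RPM, and maternal transcripts 6 and 13 of 36 (adjusted p = 0.16), with nanog falling from 442 to 294 RPM, while ybx1 rose from 1968 to 2507 RPM, pou5f3 from 1173 to 1336 RPM, ddx4 from 168 to 187 RPM and cxcr4b from 61.1 to 67.5 RPM. The median log2 changes of the germ cell and maternal lists, -0.38 and -0.30, lay below the central 95% of matched random lists, and cameraPR shifted both down at a correlation of 0.01 (adjusted p = 0.0217 and 0.0417) but not at 0.05 (0.127 and 0.215), and by rank the germ cell list alone of the 2 (0.0384, maternal 0.0951). DNA repair genes had 13 rises and 14 falls of 63, antioxidant genes 4 and 5 of 28, apoptosis genes 6 and 6 of 26, chromatin genes 21 and 17 of 69, inflammation genes 5 and 3 of 27 and retinoic acid genes 9 and 4 of 23, and none of these lists passed, though the median of the retinoic acid list (0.18) lay above the central 95% of matched random lists (-0.32 to 0.10). Among them gpx8 fell from 21.1 to 10.1 RPM and smarca2 by a log2 change of -1.20, and dhrs9 rose from 1.89 to 6.14 RPM. The gene hnf4a rose from 56.1 to 74.9 RPM, and cyp26a1 was at 24.2 and 19.3 RPM. Of the later-stage markers 3 were listed and none was called, and of the adult gonad, sperm and blood genes 3 were listed, with cyp17a1 falling from 26.5 to 16.1 RPM.

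At 0 yr the 53 and 8.7 mGy/h comparisons had 13197 genes in common and changed 9 genes up and 9 down in both, including aldh3a1, usf1l, maza and mcm3l up and rrm2, cited2, thy1 and tmprss4a down. Independent lists would share 4.03 genes up and 4.24 down (Fisher's exact test, p = 0.00994 and 0.022, and 0.0795 and 0.088 adjusted over the 8 planned overlap tests), so neither passed after adjustment. The genes fn1a and adcy8 rose at 53 mGy/h and fell at 8.7 mGy/h, and cyp2x6 fell and rose. Both comparisons use the same controls, which cannot be split with 2 libraries, so part of any excess may come from them. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.149 and Spearman's rho 0.129. The covariance was 0.0454, against 0.0341 in simulations of unchanged groups with shared controls, a difference of 0.0113, and the simulated Pearson's r was 0.60. The simulated spread came from the median absolute deviation, which gives little weight to the largest changes, while the observed covariance includes them. The difference therefore does not show a response shared beyond the controls. The simulated groups shared 0 calls in the same direction, but groups without changes have hardly any calls to share, so this does not show how much of the 18 the controls account for.

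For 8.7 mGy/h, 12171 genes were in both the 0 yr and the 1 yr table. Those changed in the same direction were 4 up, among them aldh3a1, cyp2x6 and usf1l, and 7 down, among them cited2, fn1a, jarid2b and kctd1. Independent lists would share 3.67 up and 4.11 down (Fisher's exact test, p = 0.775 and 0.154), so no excess over chance was detected. The genes rrm2 and zgc:113208 fell at 0 yr and rose at 1 yr, and maza rose and fell. Across genes Pearson's r was 0.12 and Spearman's rho 0.163. In all 3 comparisons 10 genes were called, 5 of them in the same direction, namely aldh3a1 and usf1l up and cited2, thy1 and tmprss4a down.

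The 53 mGy/h, 0 yr and 8.7 mGy/h, 1 yr comparisons, which use separate libraries, were set against each other after the data had been seen. Of 12154 genes in both tables, 3144 were called in both, and 3068 of these changed in opposite directions, among them sh2d5, etv5a, otx1b, smad2, ccna1 and hnf4a. There were 1672 genes up and then down, where independent lists would give 615, and 1396 down and then up, where they would give 540. Across genes Pearson's r was -0.613 and Spearman's rho -0.685.

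**Figure D3:**
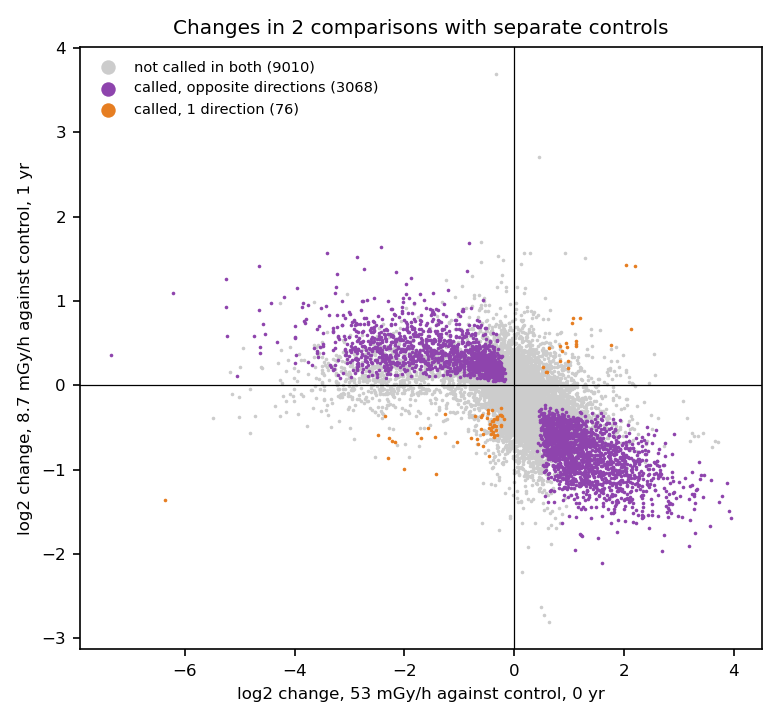
Log2 change at 53 mGy/h, 0 yr (horizontal axis) against log2 change at 8.7 mGy/h, 1 yr (vertical axis) for 12154 genes, with genes called in both coloured by whether the directions differ. Of the 3144 genes called in both, 3068 lie in the quadrants of opposite signs.

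Differences in response between comparisons could not be tested without standard errors. Between 53 and 8.7 mGy/h at 0 yr, the log2 change at 53 mGy/h was higher by at least 1 in 1943 genes and lower by at least 1 in 1676. The median difference lay below the central 95% of matched random lists in every lineage list, at -1.94 to -2.39. It was also below for ribosomal proteins (-0.49), cell cycle (-0.24) and gastrulation genes (-0.20). The p53 pathway list alone lay above (0.67, against -0.10 to 0.43). Between 8.7 mGy/h at 1 yr and 0 yr, the 1 yr change was higher by at least 1 in 145 genes and lower by at least 1 in 611. Over members listed at both times, the median difference was within the central 95% of matched random lists for mesoderm and endoderm genes (-0.06, against -0.16 to 0.09). It was also within for the enveloping layer (0.07, against -0.15 to 0.09). It was above for dorsoventral genes (0.13, against -0.17 to 0.05), ectoderm genes (0.13, against -0.23 to 0.11) and the yolk syncytial layer (0.15, against -0.26 to 0.12). Cell cycle (0.18, against -0.08 to 0.06), ribosomal protein (0.14, against -0.06 to 0.05) and gastrulation genes (0.16, against -0.15 to 0.07) lay above too. Mitochondrial (-0.24, against -0.13 to 0.14) and maternal transcripts (-0.24, against -0.20 to 0.07) lay below, and the other lists examined lay within. The gene cpeb1b had a log2 change of 0.47 at 0 yr and -1.77 at 1 yr, and rrm2 of -1.62 and 0.77.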

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

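The comparison of 53 mGy/h, 0 yr with 8.7 mGy/h, 1 yr and every test of an explanation in this part were chosen after the results had been seen, while the counts of opposite changes in the other pairs were planned. Genes that the authors' calls put in opposite directions in a pair of comparisons numbered 3068 for 53 mGy/h, 0 yr and 8.7 mGy/h, 1 yr, 3 for 53 and 8.7 mGy/h at 0 yr (fn1a, adcy8 and cyp2x6) and 3 for 8.7 mGy/h at 0 yr and 1 yr (rrm2, zgc:113208 and maza). The difference itself was not tested for any gene, because the tables give no error.

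By the Fisher test the lineage, cell cycle and ribosomal protein lists had more falls at 53 mGy/h, 0 yr and more rises at 8.7 mGy/h, 1 yr. The genes called in opposite directions were not counted by list. With cameraPR at a correlation of 0.05 the cell cycle list passed in neither comparison (adjusted p = 0.151 and 0.215), nor did the ribosomal protein list at 53 mGy/h (0.304). As the whole cause of the opposite changes, a gene span or abundance bias is argued against by the rank correlation of the log2 changes within 10 bins of genes, whose median was -0.666 by span and -0.690 by mean RPM. Span did track the changes, with Spearman's rho of 0.225 at 53 mGy/h, 0 yr and -0.248 at 8.7 mGy/h, 1 yr, so a part played by it is not excluded. Span here runs from gene start to gene end, introns included. A bias by transcript length was not examined and stays open. Different developmental timing at the same nominal age is a candidate explanation, since all 5 lineage lists had more falls at 53 mGy/h and more rises at 8.7 mGy/h, 1 yr by the Fisher test, but it stays open, because 4 did with cameraPR at a correlation of 0.05 or a mean RPM of at least 10 (mesoderm and endoderm list at 1 yr, adjusted p = 0.0712 and 0.426, over all alternatives 0.00328 to 0.426), altered zygotic transcription at an unchanged stage predicts the same, and the median of the maternal list lay below matched random lists at 1 yr (-0.30, against -0.23 to 0.07) but within them at 53 mGy/h (0.07, against -0.06 to 0.34). Variation between collections without exposure stays open, as the difference between the controls of 1 yr and 0 yr, from tables made separately, correlated across genes with the 8.7 mGy/h, 1 yr change (Spearman's rho 0.230) although their shared control pushes this below 0. With the 53 mGy/h, 0 yr change the control difference had a Spearman's rho of -0.118, although the shared 0 yr control pushes that above 0. An exchange of the group names in the 1 yr table stays open, since both groups hold 3 libraries and the agreement of the 8.7 mGy/h changes at 0 yr and 1 yr, which an exchange would reverse, was weak (Spearman's rho 0.163, 62.6% of genes called at 1 yr with the same sign at 0 yr, 11 genes called in the same direction and 3 in opposite ones). Lists were mixed as well. The medians of the ribosomal protein (0.09 and 0.21), yolk syncytial layer (0.29 and 0.50) and dorsoventral (0.03 and 0.28) lists lay above matched random lists at 0 yr and 1 yr. That of the germ cell list lay above them at 0 yr (0.08) and below at 1 yr (-0.38).

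At 8.7 mGy/h few genes were called at 0 yr and many at 1 yr. The smallest depths that fit, 27.7 and 25.7 M reads at 0 yr and 22.6 and 23.6 M at 1 yr, are lower bounds and show no lower depth at 0 yr. The smaller number of control libraries at 0 yr or any lower depth there could act as noise independent between genes. For the genes called at 1 yr, such noise is argued against as the whole cause. The 0 yr changes of 5132 genes called at 1 yr had a slope of 0.0708 on the 1 yr changes (95% interval over resampled genes 0.0565 to 0.0857). Resampling genes does not cover an offset of many genes together in the 0 yr control libraries, which stays open. Nor does the slope show whether fewer control libraries hid changes at 0 yr in genes not called at 1 yr. The same control libraries gave 5978 calls at 53 mGy/h, but of larger changes (median fold 2.24 up and 2.41 down, against 1.25 and 1.64 at 1 yr). Those calls do not show that changes of the 1 yr size could be called at 0 yr. Time since exposure, parental age and breeding day changed together between the collections and stay open, as untested.

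Ribosomal protein genes fell at 53 mGy/h, 0 yr and rose at 8.7 mGy/h, 1 yr. Their short span is argued against as the whole cause, since their median lay at percentile 0 of 10000 random lists matched on span and mean RPM at 53 mGy/h and at percentile 100 at 8.7 mGy/h, 1 yr, with either 20 or 5 bins of span. Because span counts introns, this does not test a bias by transcript length, which stays open. A scaling factor would move the matched lists of the same table alike, and the list's median lay outside their central 95% by at least 0.0683 on the log2 scale in both comparisons, which argues against it as the whole cause. The random lists were drawn gene by gene, so for a co-regulated list these positions look more extreme than they are. With cameraPR at a correlation of 0.05 the list passed at 1 yr (adjusted p = 0.0133) but not at 53 mGy/h (0.304). RNA composition of whole embryos and the developmental timing weighed above stay open, and no library value shows how the list varies between clutches.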

How the results depend on the processing

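The alternatives fixed before the data were examined were an FDR under 0.01 or 0.1 and a log2 change of at least 1 for the counts of called genes, an FDR under 0.01 and a log2 change of at least 1 for the overlaps with 8.7 mGy/h, 0 yr, and centring for response differences. All others, including every one for the opposite changes and the lists, were chosen after seeing the data. No paired analysis was possible because the deposited tables hold one pooled value per group. For the same reason leaving out replicates, other splits of the samples, other normalizations or count models, low-count filters, pseudocounts, single against joint fits and an estimated correlation were not run, nor, for lack of unadjusted p, standard errors or statistics, were recomputed adjustments, centred tests and removal of the shared-control covariance.

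An FDR under 0.1 and leaving out numbered copies kept every count of called genes within 1.5 times. Centring cannot change which genes are called, since the FDR is as deposited, so it says nothing about their stability. Nor can it change the direction of calls at 53 mGy/h, 0 yr and 8.7 mGy/h, 1 yr, since no called gene there lay between 0 and the centre of the calls. At 8.7 mGy/h, 0 yr that centre was not estimated. At an FDR under 0.01, 8.7 mGy/h, 0 yr had 23 genes (13 up, 10 down), the overlap with 53 mGy/h 11 and that with 1 yr 6. With a log2 change of at least 1, 53 mGy/h had 3565 genes (1864 up, 1701 down), 8.7 mGy/h, 0 yr 22 (13 up, 9 down) and 1 yr 728 (130 up, 598 down), the overlaps held 7 and 2 genes and the opposite changes 436. These fall because fewer genes meet the criterion. With a mean RPM of at least 10, fewer genes were counted: 3281 (1864 up, 1417 down) at 53 mGy/h, 21 (9 up, 12 down) at 8.7 mGy/h, 0 yr and 3283 at 1 yr (1776 up, 1507 down), with 7 genes shared by the 8.7 mGy/h comparisons, 1665 opposite changes, and 1114 and 129 genes whose changes differed by at least 1 between dose rates and between times.

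Of the lists, 9 fell at 53 mGy/h and 9 rose and 1 fell at 8.7 mGy/h, 1 yr by the Fisher test. With a mean RPM of at least 10, 6 rose and 0 fell at 1 yr, and the lists of gastrulation movements (adjusted p = 0.426), mesoderm and endoderm (0.426), heat shock (0.136) and mitochondrial transcripts (0.0834) no longer passed there. With cameraPR at a correlation of 0.01, 1 list rose at 53 mGy/h (p53 pathway), 4 rose and 1 fell at 8.7 mGy/h, 0 yr, and 2 fell at 1 yr (maternal transcripts and germ cell). At 0.05, 5 fell at 53 mGy/h, 2 rose at 8.7 mGy/h, 0 yr, and 5 rose and 0 fell at 1 yr. By rank, 1 rose at 53 mGy/h (p53 pathway) and 2 at 8.7 mGy/h, 0 yr, and the germ cell list fell at 1 yr (adjusted p = 0.0384) in place of the mitochondrial list (0.148), as it did at an FDR under 0.01 (0.026). At an FDR under 0.01 the mitochondrial list no longer had more falls than other genes at 53 mGy/h (adjusted p = 0.962, over all alternatives 0.0247 to 0.962), and at 1 yr it (0.144) and the gastrulation list (0.234) no longer passed. Over the alternatives that could move them, the adjusted p at 1 yr was 0.0834 to 0.503 for the mitochondrial list, 0.084 to 0.426 for gastrulation, 0.00411 to 0.184 for heat shock and 0.00328 to 0.426 for mesoderm and endoderm. The cause was not tested for these losses and gains and the cameraPR results. Geometric mean depth was at least 22.6 to 27.7 M reads per group, and how depth limits single genes could not be tested on pooled values.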

Other observations

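The control groups of the collections had different medians in most of the lists described above. From 0 yr to 1 yr, with tables made separately, the median log2 RPM of the yolk syncytial layer list was 0.85 higher in controls, that of the enveloping layer list 0.77, dorsoventral genes 0.50, ribosomal proteins 0.36, mesoderm and endoderm genes 0.31 and ectoderm genes 0.21. The differences were negative for inflammation (-0.46), antioxidant (-0.39), germ cell (-0.37), apoptosis (-0.35), p53 pathway (-0.31), DNA repair (-0.30), maternal (-0.26), chromatin (-0.21), cell cycle (-0.21), heat shock (-0.20), mitochondrial (-0.16) and gastrulation (-0.12) lists, and 0.01 for the retinoic acid list. In the 8.7 mGy/h groups the lists in the same order differed by 0.98, 0.83, 0.66, 0.52, 0.44, 0.35, -0.48, -0.48, -0.74, -0.53, -0.40, -0.30, -0.63, -0.21, -0.03, -0.06, -0.40, 0.06 and 0.01. Across 12171 genes, which are not independent replicates, the differences between collections in controls and in 8.7 mGy/h groups had Pearson's r of 0.722 and Spearman's rho of 0.672. A difference of at least 1 was found for 1028 genes in controls and 2354 in the 8.7 mGy/h groups. The median changes at 8.7 mGy/h, 1 yr, over all members listed there, were 0.50 in the yolk syncytial layer list, 0.31 in the enveloping layer and 0.28 in dorsoventral genes. They were 0.21 in ribosomal proteins, 0.12 in mesoderm and endoderm genes and 0.23 in ectoderm genes. Among these lists the exposure change exceeded the control difference in ectoderm genes alone, narrowly (0.23 and 0.21) and over unlike members. Among the other lists it was larger in size for mitochondrial (-0.34 and -0.16), maternal (-0.30 and -0.26) and germ cell genes (-0.38 and -0.37). It was also larger for the retinoic acid list (0.18 and 0.01). The differences between collections were not set beside matched random lists, and no test against the spread between libraries was possible.

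The mitochondrially encoded list had a median log2 change of -0.22 at 53 mGy/h, 0 yr, -0.34 at 8.7 mGy/h, 1 yr and -0.09 at 8.7 mGy/h, 0 yr, with 7 of 13 transcripts called lower in each of the first 2. Its Fisher test passed in both, but not at an FDR under 0.01 (adjusted p = 0.962 and 0.144) nor with cameraPR at a correlation of 0.01 (0.672 and 0.382) or 0.05 (0.784 and 0.503). At 53 mGy/h it also passed with a mean RPM of at least 10 (0.0247) and with cameraPR by rank (0.0338), and at 1 yr with neither (0.0834 and 0.148).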
